A study of Mus musculus with 16 samples.

How the data were processed

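RNA was sequenced from hearts of 16 mouse embryos, 4 of each of 4 genotypes, as total RNA from a column kit and stranded libraries per the labels. The deposited values were raw counts of reads per gene, with 1 table for the series and 16 tables of single samples. The deposited gene length in bases (other) was not used. All 16 single-sample tables were equal to the series table. Per the submitters' processing notes, bcl2fastq, featureCounts (versions not given) and the mm10 build were used; the aligner and the annotation are not given in the sources used here. The table held 27179 gene IDs, of which 25275 (93.0%) were matched to a symbol and a position, and the 1904 others took 2.08% of the reads. Total counts ranged from 19753100 to 35664331 per library.

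Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter for low counts kept 15785 genes, removed 11394 and kept 100.0% of the reads. TMM factors ranged from 0.967 to 1.08. A quasi-likelihood model of the 4 group means was fitted to all 16 libraries, and 5 pairwise comparisons and the interaction were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The biological coefficient of variation was 0.159. CPM values used TMM-scaled library sizes, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. Pairs of libraries of the same genotype differed by a chi-square per degree of freedom of 6.68 to 108, so the spread between embryos exceeded counting error.

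The choices of test, gene lists, named genes and alternatives were made before the data were examined, except those said to be added later. Of 30 gene lists, 29 were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, and p-values were adjusted over the lists of a comparison. Lists with fewer than 3 measured members were not tested, so the mitochondrially encoded genes, absent from the table, were not analysed here. The 29 lists covered cell types and regions of the heart, other tissues, blood, chromatin complexes and cell functions, and the result of each is given for Ing4+/- Ing5-/- against wild-type hearts. Genes to name were the 10 called genes with the largest rise and the 10 with the largest fall in each comparison. These had to have a mean of at least 1 CPM and no overlap between the groups. Ing4, Ing5, genes within 10 Mb of either, sex-linked markers and predicted genes were left out there. Called genes near the targets and up to 4 called members of each list were named too, and Ing4, Ing5, Wt1, Tbx18, Tcf21, Aldh1a2 and Upk3b always. Cox4i2, Dpp6 in other comparisons, the Xlr genes and the genes of single libraries were chosen after their values were seen where the rule did not name them.

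Alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in 4 libraries, only the groups compared, the DESeq2 Wald test, limma-voom, litter as a block or a random effect, replicate number as a block and the level of Y-linked genes as a covariate. Others were litter with that covariate, haemoglobin genes left out, genes near the targets left out, distances of 5 and 20 Mb, and leaving out each library in turn. Added after seeing the data were a fit without the 3 libraries that stood apart on the principal components (25.3, 14.7 and 12.3% of the variance), the level of haemoglobin genes as a covariate, and leaving out libraries of the groups not compared. The 3 libraries were Ing4+/- 4, Ing5-/- 1 and Ing4+/- Ing5-/- 2. Litter was not part of the main model, since no source used here states that the study modelled it and no litter held both Ing5-/- and wild-type embryos. Residuals of libraries with the same replicate number correlated above 0.1 in 5 of 24 pairs (median 0.020), and those of the same litter in 3 of 11 pairs (median 0.024), so replicate numbers were not taken as pairs.

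The pipeline was tested on simulated data with the design of Ing4+/- Ing5-/- against wild-type hearts and 15615 genes. It recovered 41 of 66 genes changed 1.5-fold (62.1%), 46 of 67 changed 2-fold (68.7%) and 55 of 64 changed 3-fold (85.9%). It called 6 of 15418 unchanged genes, the 1 changed list and 0 of 20 unchanged lists. The simulated genes varied independently, with no litter effect and no library that stood apart, so these shares are not the power of the real comparison. The result for unchanged lists holds for the simulated data only and does not show how often camera calls such lists in real hearts. In regroupings with 2 Ing4+/- Ing5-/- and 2 wild-type hearts on either side, camera called 1 to 11 lists each.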

Results

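Gene expression was measured by RNA sequencing in hearts of mouse embryos at embryonic day 10.5. The 16 hearts belonged to 4 genotypes with 4 embryos each: wild-type, Ing4+/- (1 Ing4 allele lost), Ing5-/- (both Ing5 alleles lost) and Ing4+/- Ing5-/- (3 of the 4 alleles lost). Ing4 and Ing5 encode related proteins that read methylated histone H3 and belong to histone acetyltransferase complexes. The title of the series names the development of the epicardium, the cell layer that covers the heart, as one subject of the study. The libraries held between 19753100 and 35664331 counted reads, and 15785 genes were tested. The hearts came from 7 litters, and no litter held both a wild-type and an Ing5-/- embryo. Values below are read counts scaled to the library size (CPM) as mean ± SD with n = 4, or log2 fold changes ± SE from edgeR.

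The reads of the targeted genes were compared first, since they follow from the genotype labels. Ing5 (gene ID 66262, chromosome 1: 93803926 to 93822101, GRCm38) stood at 33.5 ± 3.46 CPM in wild-type and 37.2 ± 3.70 CPM in Ing4+/- hearts. It stood at 23.5 ± 4.48 CPM in Ing5-/- and 21.0 ± 2.75 CPM in Ing4+/- Ing5-/- hearts. Ing5 fell by 0.68 ± 0.13 in Ing4+/- Ing5-/- hearts against wild-type (edgeR adjusted p = 0.0122; 0.204 with litter as a block). It fell by 0.82 ± 0.12 against Ing4+/- hearts (adjusted p = 0.00169; 0.0131 with litter as a block). The difference between Ing5-/- and wild-type hearts was -0.51 ± 0.12 and did not pass the threshold with edgeR (adjusted p = 0.275), but did with DESeq2 (0.0449). Ing5-/- 1 had 29.3 CPM, within the wild-type range of 28.9 to 36.9, and the other 3 Ing5-/- hearts had 18.5 to 23.7 CPM. Ing4 (gene ID 28019, chromosome 6: 125039848 to 125049265) stood at 39.5 ± 7.60 CPM in wild-type, 34.1 ± 1.85 in Ing4+/-, 51.0 ± 7.31 in Ing5-/- and 34.3 ± 1.90 in Ing4+/- Ing5-/- hearts. Its difference was -0.21 ± 0.12 between Ing4+/- and wild-type hearts (edgeR adjusted p = 0.963) and -0.57 ± 0.12 between Ing4+/- Ing5-/- and Ing5-/- hearts (0.256). The latter passed with DESeq2 (adjusted p = 0.0163) and with edgeR without wild-type 2 (0.0295), which had an Ing4 level of 28.2 CPM. The other wild-type hearts had 42.6 to 44.4 CPM and the Ing4+/- hearts 32.0 to 36.3 CPM, so wild-type 2 made the difference between these 2 genotypes smaller. Counts were summed over whole genes, and the sources used here do not give the deleted parts, so residual reads do not measure residual protein.

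**Figure D1:**
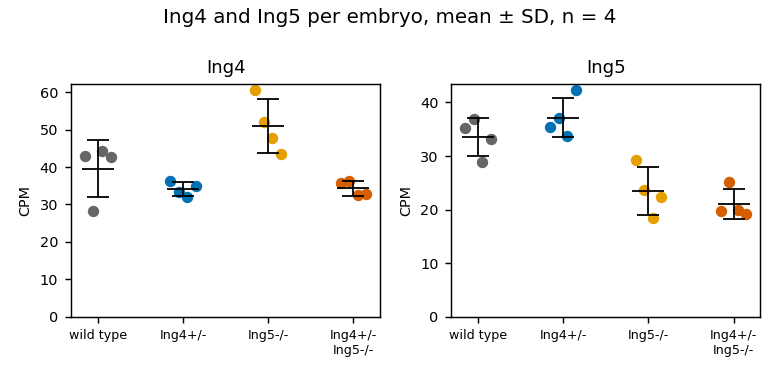
Expression of Ing4 and Ing5 (CPM, linear axis from 0) in the 4 genotypes; each point is 1 embryo and bars show mean ± SD, n = 4. Ing5 stood at 21.0 ± 2.75 CPM in Ing4+/- Ing5-/- hearts and at 33.5 ± 3.46 CPM in wild-type hearts, and Ing4 varied between 28.2 and 44.4 CPM among wild-type hearts.

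The comparison of Ing4+/- Ing5-/- with wild-type hearts asks how the loss of 3 of the 4 alleles changed expression. Of 25 genes of the response to low oxygen and of glycolysis, 7 rose and 18 were not called (camera adjusted p = 6.04e-21 for the list; adjusted p = 0.0951 with an estimated correlation). Vegfa, the main growth factor for blood vessels, went from 100.003 ± 8.65 to 197 ± 29.8 CPM (log2 fold change 0.98 ± 0.12, edgeR adjusted p = 0.000524). Egln3, an oxygen-sensing prolyl hydroxylase, went from 11.8 ± 1.33 to 26.8 ± 3.30 CPM (1.18 ± 0.14, adjusted p = 0.000273). Of 18 genes of macrophages 8 rose, among them Laptm5, a lysosomal membrane protein of blood cells, from 7.42 ± 1.36 to 18.6 ± 2.49 CPM (1.32 ± 0.19, adjusted p = 0.00147). Hap1, a huntingtin-associated protein, fell by 1.18 ± 0.17 from 11.3 ± 1.02 to 4.97 ± 0.85 CPM (adjusted p = 0.00147; 0.122 with litter as a block).

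Of the 15785 genes, edgeR called 110 higher and 25 lower, 135 in all, and 1793 had an unadjusted p under 0.05. DESeq2 called 325 genes and limma-voom 78. For 134 of the 135 genes every heart of one genotype lay above every heart of the other. That held for 10.2% of all genes, and chance gives 2.86%. The 135 were called on these same hearts, so neither their separation nor their direction in another fit of these hearts is further support. With litter as a block 15 genes were called, 14 of them among the 135, and all 135 kept their direction. Litters 4 and 6 each held 1 heart of both genotypes, and values within them are given below for gene lists. These values come from the same hearts as the full comparison, so they are not independent of it. Xist, of the inactive X chromosome, was high in Ing4+/- Ing5-/- 2 of litter 4 (595 CPM) and wild-type 4 of litter 6 (398 CPM). Their littermates, wild-type 1 and Ing4+/- Ing5-/- 3, had the Y-linked Ddx3y instead (71.0 and 66.4 CPM). Each pair thus differed in sex markers too, in opposite ways. The count of 135 genes fell to 44, 77 and 82 without Ing4+/- Ing5-/- 2, 3 and 4, to 60, 60, 37 and 41 without wild-type 1, 2, 3 and 4, and rose to 321 without Ing5-/- 1. The share of higher genes was 81.5%, against 67.0% without Ing5-/- 1.

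In the list of 25 glycolysis and hypoxia genes, 7 rose, none fell and 18 were not called, while 21 were higher when adjusted over the list alone. The median log2 fold change was 0.44, and camera placed the list above other genes (adjusted p = 6.04e-21), with adjusted p = 0.0951 with an estimated correlation. Fry, which asks whether the members move one way, gave an adjusted p of 0.00353. Besides Egln3 and Vegfa, Aldoc, a glycolytic aldolase, rose by 1.20 ± 0.19 (adjusted p = 0.00403). Pgk1, phosphoglycerate kinase, rose by 0.56 ± 0.11 from 158 ± 24.5 to 232 ± 20.7 CPM (0.0183). Pgk1 lost its call without Ing4+/- Ing5-/- 2 (0.0768) or 4 (0.0537) and without wild-type 3 (0.0822) or 4 (0.0716). The median was 0.51 within litter 4 and 0.39 within litter 6. With litter as a block 2 members were called, Egln3 (adjusted p = 0.0132) and Aldoc (0.0224), and Vegfa (log2 fold change 0.92, 0.154) and Pgk1 (0.44, 0.456) were not, while 17 members were called without Ing5-/- 1. Outside the list, Ndufa4l2, a mitochondrial protein induced by low oxygen, rose by 2.96 ± 0.42 from 2.05 ± 1.06 to 16.2 ± 4.69 CPM (adjusted p = 0.00294; 0.200 with litter as a block).

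In the list of 18 macrophage genes, 8 rose, none fell and 10 were not called, and 15 were higher when adjusted over the list alone. The median log2 fold change was 2.15 and camera placed the list above other genes (adjusted p = 1.04e-19), with adjusted p = 0.120 with an estimated correlation. Fry gave an adjusted p of 0.00552. Laptm5 and Ptprc, the leukocyte antigen CD45 (3.69 ± 0.61, edgeR adjusted p = 0.00480), kept their call without each library in turn. Cx3cr1, the fractalkine receptor, rose from 0.827 ± 0.207 to 4.63 ± 0.69 CPM (2.46 ± 0.46, adjusted p = 0.0137). Its call was lost without wild-type 1 (0.0510), 3 (0.0728) or 4 (0.0677). Spi1, the transcription factor PU.1, rose by 2.20 ± 0.45 (adjusted p = 0.0229; 0.298 with litter as a block). Its call was lost without Ing4+/- Ing5-/- 2 (0.0838) or 3 (0.0521) and without wild-type 2 (0.0670), 3 (0.0871) or 4 (0.0827). Fcrls, an Fc receptor-like gene of macrophages and microglia outside the list, rose from 0.139 ± 0.122 to 2.59 ± 0.36 CPM (4.28 ± 0.62, adjusted p = 0.00147). The median of the list was 1.93 within litter 4 and 2.63 within litter 6. With litter as a block 1 member was called, Cx3cr1 (adjusted p = 0.0224), while Laptm5 (log2 fold change 1.33, adjusted p = 0.0941), Ptprc (3.87, 0.242) and Fcrls (3.28, 0.154) were not, and without Ing5-/- 1 there were 11. Haemoglobin transcripts made up 2.22 ± 1.70% of the reads in Ing4+/- Ing5-/- and 1.02 ± 0.162% in wild-type hearts. The first mean rests in part on Ing4+/- Ing5-/- 2 (4.68%), and the others of its group had 0.768 to 1.82%.

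**Figure D2:**
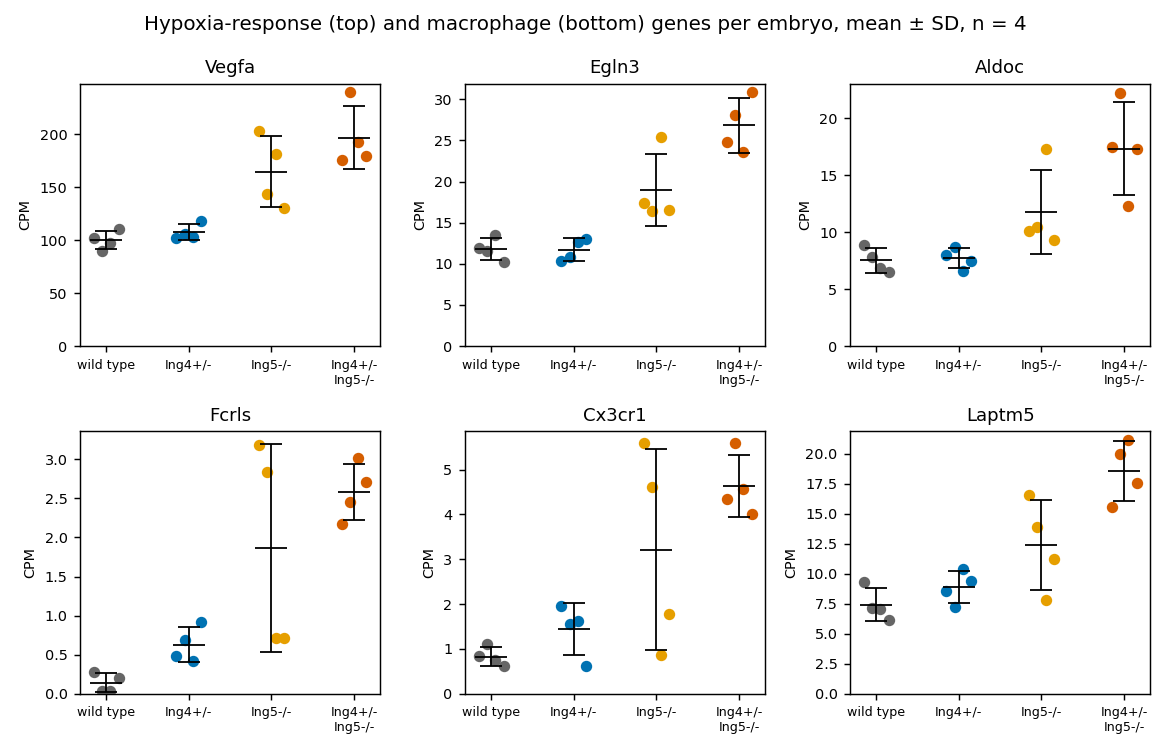
Expression (CPM, linear axes from 0) of the hypoxia-response genes Vegfa, Egln3 and Aldoc and the macrophage genes Fcrls, Cx3cr1 and Laptm5 in the 4 genotypes; each point is 1 embryo and bars show mean ± SD, n = 4. For each of the 6 genes the 4 Ing4+/- Ing5-/- hearts lay above the 4 wild-type hearts, and Egln3 stood at 26.8 ± 3.30 against 11.8 ± 1.33 CPM.

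Epicardial genes were lower as a list by camera at the preset correlation, but not by fry in one direction, and single members were mostly not called. Of 28 measured members 22 had a negative log2 fold change, with a median of -0.29. Camera placed the list below other genes (adjusted p = 0.00393; adjusted p = 0.712 with an estimated correlation). The camera call was lost without Ing4+/- Ing5-/- 2 (median -0.22, adjusted p = 0.0586) and with the haemoglobin level as a covariate (-0.20, 0.0954). Only Krt19, a keratin of the mesothelium, was called, and it rose by 0.71 ± 0.12 from 49.1 ± 3.49 to 80.3 ± 8.73 CPM (edgeR adjusted p = 0.00501; 0.0941 with litter as a block). Adjusted over the list alone, 1 member was higher and 3 were lower. Tcf21, a transcription factor of epicardial cells, stood at 30.6 ± 5.83 against 49.0 ± 5.58 CPM (-0.68 ± 0.35, adjusted p = 0.501). Upk3b, a uroplakin of mesothelial cells, stood at 113 ± 18.5 against 168 ± 7.45 CPM (-0.57 ± 0.37, adjusted p = 0.610). Tbx18, a T-box factor, stood at 80.7 ± 8.44 against 104 ± 5.46 CPM (-0.36 ± 0.30, adjusted p = 0.706). Wt1, the Wilms tumour factor, stood at 57.2 ± 4.03 against 67.7 ± 0.907 CPM (-0.24 ± 0.26, adjusted p = 0.787). Aldh1a2, which makes retinoic acid, stood at 27.5 ± 5.85 against 37.9 ± 4.10 CPM (-0.46 ± 0.44, adjusted p = 0.756). For Tcf21, Upk3b, Tbx18 and Wt1 the 4 hearts of one genotype did not overlap with the 4 of the other.

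The calls of these genes differed between fits. Ing5-/- 1 had 106 CPM of Tcf21, 388 CPM of Upk3b and 150 CPM of Wt1, above every other heart, and it entered the shared estimate of the spread. In a fit of the Ing4+/- Ing5-/- and wild-type hearts alone, 11 epicardial members were called lower and 2 higher. There Tcf21 (edgeR adjusted p = 0.0104), Upk3b (0.00422) and Tbx18 (0.0116) passed, while Wt1 (0.0501) and Aldh1a2 (0.0860) did not. Leaving out Ing5-/- 1 did not bring Tcf21 (0.0892), Upk3b (0.232), Tbx18 (0.0696), Wt1 (0.201) or Aldh1a2 (0.464) past the threshold, nor did leaving out the 3 libraries that stood apart (0.0844, 0.334, 0.168, 0.349 and 0.602). Without Ing5-/- 1, 2 other members were lower, Scx (-1.0, adjusted p = 0.0435) and Itga4 (-0.67, 0.00408), which encode scleraxis and the alpha 4 integrin. The median of the list was -0.42 within litter 4 and -0.13 within litter 6, and -0.27 with litter as a block (camera adjusted p = 0.00896).

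**Figure D3:**
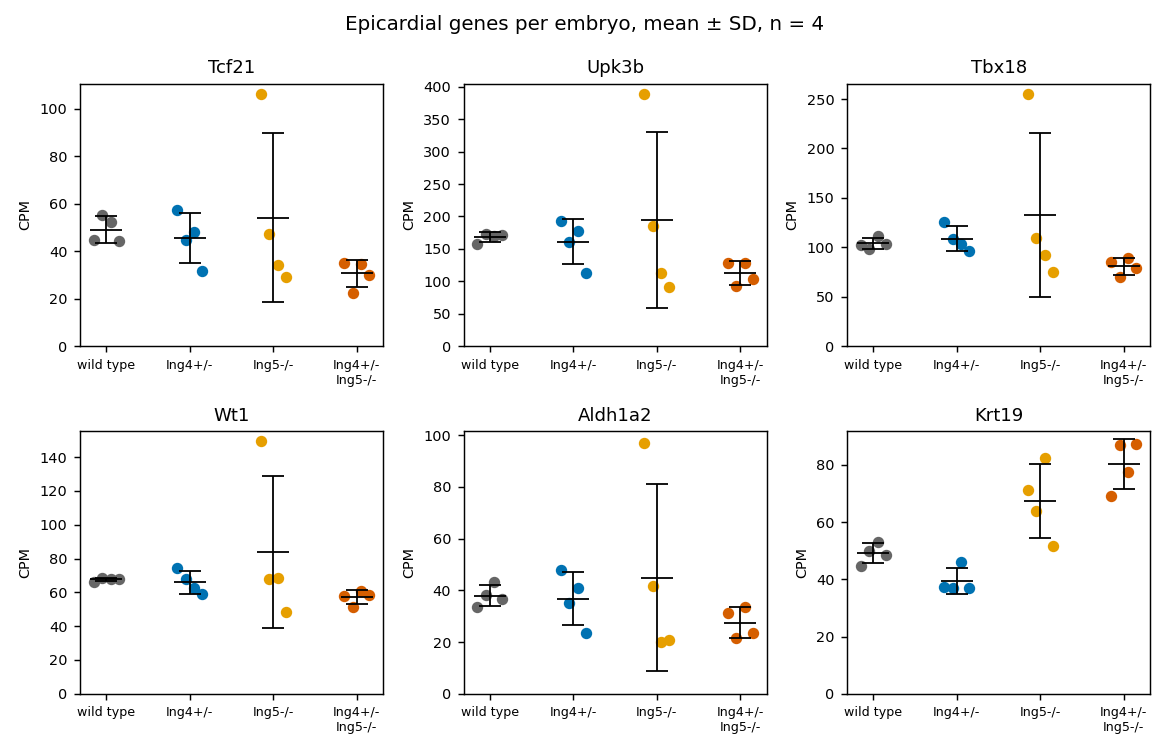
Expression (CPM, linear axes from 0) of Tcf21, Upk3b, Tbx18, Wt1, Aldh1a2 and Krt19 in the 4 genotypes; each point is 1 embryo and bars show mean ± SD, n = 4. Tcf21 stood at 30.6 ± 5.83 CPM in Ing4+/- Ing5-/- and 49.0 ± 5.58 CPM in wild-type hearts, and the highest Ing5-/- point in the first 5 panels is Ing5-/- 1.

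Among other cell types of the heart, 26 cardiomyocyte genes had a median log2 fold change of -0.10 and none was called (camera adjusted p = 0.00267; adjusted p = 0.712 with an estimated correlation). The 15 genes of the trabecular myocardium had a median of -0.14 (camera adjusted p = 0.00702; adjusted p = 0.712 with an estimated correlation; 0.220 with litter as a block). In the proepicardium and septum transversum list of 18 genes, 1 fell, with 4 lower when adjusted over the list alone (median -0.21, camera adjusted p = 0.00243; adjusted p = 0.512 with an estimated correlation). The member that fell was Mab21l2 (-0.64 ± 0.13, edgeR adjusted p = 0.0244; 0.354 with litter as a block). Its call was lost without Ing4+/- Ing5-/- 2 (0.10) or 3 (0.0712) and without wild-type 3 (0.118) or 4 (0.0885). None of 23 endothelial and endocardial genes was called, 4 were higher when adjusted over the list alone, and the median was 0.21 (camera adjusted p = 9.64e-05; adjusted p = 0.564 with an estimated correlation). All 18 erythroid genes had positive values with a median of 1.05, and none was called (camera adjusted p = 0.00153; adjusted p = 0.712 with an estimated correlation). Camera called none of the lists for compact myocardium (median 0.02), atrium and inflow (-0.13), outflow tract and second heart field (0.14), cushion mesenchyme (-0.04), neural crest (-0.06) and neurons (-0.18). It also did not call endoderm and liver bud (0.54), skeletal and pharyngeal muscle (-0.41), Hox genes (-0.07), T-box genes (0.02) and extracellular matrix (0.01). Without Ing4+/- Ing5-/- 2 camera called neither the cardiomyocyte (adjusted p = 0.0811), the trabecular (0.0683), the proepicardium (0.0501) nor the erythroid list (median 0.44, 0.193), and without Ing4+/- Ing5-/- 1 it did not call the trabecular list (0.0534). The median, the mean and the direction of the test differed in sign for compact myocardium, neural crest, T-box genes, the ING and MYST complexes, the retinoic acid pathway and extracellular matrix, none of which was called.

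Of the lists for cell functions, 25 mitotic genes had a median of -0.10, with none called (camera adjusted p = 3.35e-05; adjusted p = 0.609 with an estimated correlation). The 26 DNA replication genes had a median of -0.07 with 1 lower when adjusted over the list alone, Rrm2 (camera adjusted p = 0.0126; adjusted p = 0.712 with an estimated correlation; 0.599 with litter as a block). All 26 oxidative phosphorylation genes had negative values with a median of -0.07 (camera adjusted p = 0.00153; adjusted p = 0.712 with an estimated correlation; 0.122 with litter as a block). The 33 ribosomal protein genes had a median of 0.12 (camera adjusted p = 0.00153; adjusted p = 0.712 with an estimated correlation). The 20 immediate early genes had a median of 0.19 (camera adjusted p = 0.00335; adjusted p = 0.512 with an estimated correlation). Camera did not call the p53 targets (median -0.07), the retinoic acid pathway (-0.09), the ING and MYST complexes (0.01), the growth factor signalling list (0.04) or the Y-linked genes with Xist (0.52). In the ING and MYST list of 17 genes Ing5 fell and no other member was called. Among 24 p53 targets, Perp, a desmosomal protein, fell by 0.38 ± 0.08 (edgeR adjusted p = 0.0245; 0.296 with litter as a block; 0.118 without Ing4+/- Ing5-/- 2). Among 33 genes of BMP, TGF-beta, FGF and WNT signalling, Tgfb1 rose by 0.47 ± 0.10 (edgeR adjusted p = 0.0318; 0.0224 with litter as a block; 0.148 without Ing4+/- Ing5-/- 2). Perp and Tgfb1 also lost their calls without Ing4+/- Ing5-/- 3 (0.0628 and 0.0924) or 4 (0.0664 and 0.0882) and without wild-type 1 (0.0867 and 0.112), 2 (0.0716 and 0.0840), 3 (0.0894 and 0.111) or 4 (0.0716 and 0.105). Camera did not call the oxidative phosphorylation list without Ing4+/- Ing5-/- 2 (adjusted p = 0.0811) or wild-type 2 (0.0643), the ribosomal list without Ing4+/- Ing5-/- 2 (0.107) or wild-type 4 (0.0764), or the DNA replication list without Ing4+/- Ing5-/- 4 (0.217). Over all 29 lists, camera called 6 higher and 7 lower, fry called 2 in one direction and 7 in either direction, and none was called with an estimated correlation.

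The genes with the largest rises by the naming rule were Fcrls, C1qc and C1qa of the complement system (log2 fold change 4.12 and 3.97), Fmr1nb (3.52), Kcne3 (3.28), Ndufa4l2, F13a1 (2.77), Myo1f (2.66), Fcgr3 (2.63) and Cx3cr1. The largest falls were in Nup62cl (-1.38), Hap1, Itgb8 (-0.87), Lrrn2 (-0.86), Car3 (-0.79), Strip2 (-0.76), Igfbpl1 (-0.75), Zfhx3 (-0.71), Arrdc4 (-0.67) and Map3k8 (-0.66). Zfhx3, a homeobox transcription factor, fell from 21.4 ± 2.32 to 13.1 ± 1.41 CPM (edgeR adjusted p = 0.00476; 0.165 with litter as a block). Of the 37 called genes that the rule named, 15 kept their call without each library in turn and 6 kept it with litter as a block. The 6 were Cx3cr1, Arrdc4, A2m, Egln3, Aldoc and Tgfb1. Of these 20 genes Fcrls, Fmr1nb, Kcne3, Ndufa4l2, Hap1 and Zfhx3 kept their call without each library. The highest adjusted p of the other 14 ranged from 0.0588 (Myo1f without wild-type 4) to 0.161 (Car3 without Ing4+/- Ing5-/- 2 or wild-type 3).

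**Figure D4:**
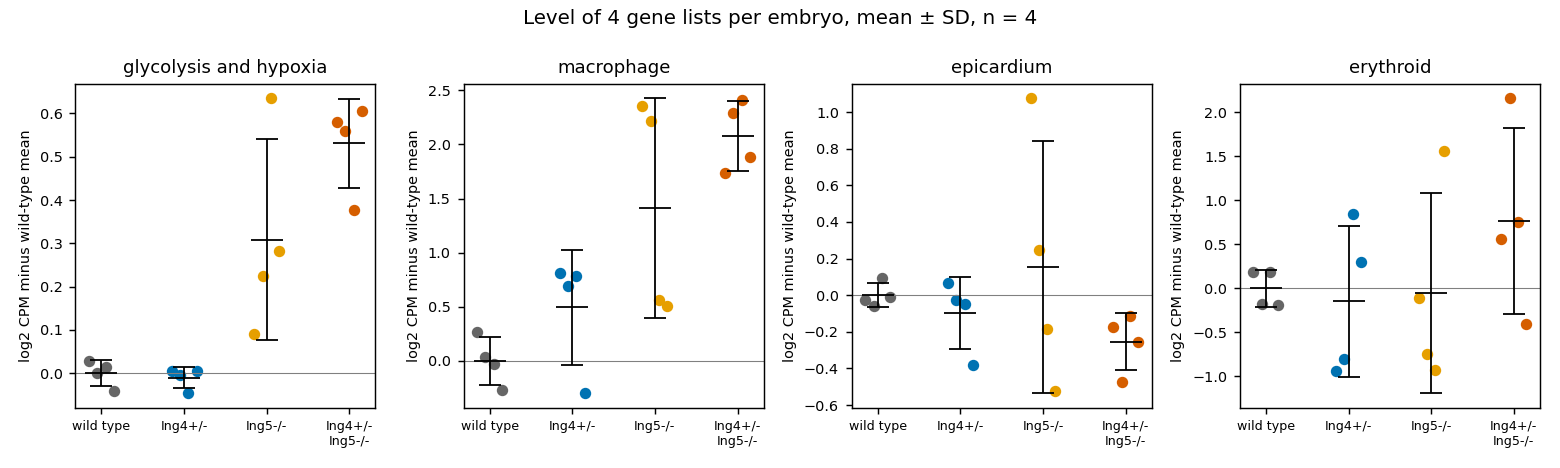
Level of the glycolysis and hypoxia, macrophage, epicardium and erythroid lists per embryo (mean over the members of log2 CPM, minus the wild-type mean; linear axes) in the 4 genotypes; each point is 1 embryo and bars show mean ± SD, n = 4. The 4 Ing4+/- Ing5-/- hearts lay between 0.38 and 0.60 in the first panel and between 1.73 and 2.41 in the macrophage panel, and the erythroid panel shows the spread within genotypes.

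Ing4+/- Ing5-/- and Ing4+/- hearts differ by both Ing5 alleles on a background with 1 Ing4 allele. Glycolysis and hypoxia genes were again higher: 12 of 25 rose, none fell, and 20 were higher when adjusted over the list alone. Their median was 0.51 (camera adjusted p = 1.38e-19; adjusted p = 0.119 with an estimated correlation; fry 0.00215). Egln3 rose by 1.19 ± 0.14 (edgeR adjusted p = 0.000174), Aldoc by 1.17 ± 0.19 (0.00360), Vegfa by 0.88 ± 0.12 (0.00105) and Pfkl, phosphofructokinase, by 0.64 ± 0.12 (0.0104). These 4 genes kept their call without each library in turn and with litter as a block (0.00142, 0.00254, 0.0417 and 0.0474). The list median was 0.50, 0.39 and 0.60 within litters 4, 6 and 7, each with 1 heart of both genotypes, and 7 members were called with litter as a block. Ing4+/- 2 of litter 4 had Ddx3y (68.6 CPM) and Ing4+/- 3 of litter 6 had Xist (372 CPM), so these pairs again differed in sex markers. Of 18 macrophage genes 2 rose, Laptm5 (1.06 ± 0.19, adjusted p = 0.00681) and Csf1r, the receptor for macrophage growth factor (1.84 ± 0.42, 0.0441), with 13 higher when adjusted over the list alone. With litter as a block 3 members were called, and without Ing5-/- 1 there were 6. Csf1r lost its call in 11 of the 16 fits that left out 1 library, with the highest adjusted p of 0.123 without Ing4+/- 2. The median of the macrophage list was 1.59 (camera adjusted p = 6.20e-12; adjusted p = 0.334 with an estimated correlation) and 1.84, 1.62 and 1.56 within the 3 litters. Litter 4 rests on Ing4+/- Ing5-/- 2 and litter 7 on Ing4+/- 4, both among the 3 libraries that stood apart. The macrophage list stood at -0.30 in Ing4+/- 4 against 0.69 to 0.81 in the other Ing4+/- hearts. Haemoglobin transcripts made up 1.11 ± 0.689% of the reads in Ing4+/- hearts.

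In the epicardium list 1 of 28 members rose in this comparison, Krt19, by 1.03 ± 0.12 from 39.4 ± 4.51 to 80.3 ± 8.73 CPM (edgeR adjusted p = 0.000174; 0.00292 with litter as a block). The median was -0.21 and camera did not call the list (adjusted p = 0.116), but did with litter as a block (median -0.27, adjusted p = 0.0225). It also called the list without Ing4+/- 4 (-0.29, adjusted p = 0.0226) and without Ing5-/- 1 (-0.21, adjusted p = 0.00606). With all libraries the list had an adjusted p = 0.804 with an estimated correlation. Within litters 4, 6 and 7 the median was -0.49, -0.17 and 0.01. Sox18, an endothelial transcription factor, rose by 0.79 ± 0.15 (edgeR adjusted p = 0.00991; 0.0639 with litter as a block). In the endothelial list 7 of 23 members were higher when adjusted over the list alone (median 0.26, camera adjusted p = 2.14e-05; adjusted p = 0.509 with an estimated correlation). Hap1 (-1.22 ± 0.17, adjusted p = 0.000906) and Pcdhgc4, a clustered protocadherin (-1.42 ± 0.26, 0.00884), fell. Dpp6, a subunit of potassium channels (2.37 ± 0.21, adjusted p = 8.67e-06), H2-Ab1, a class II histocompatibility chain (2.03 ± 0.31, 0.00244), Kcne3, another channel subunit (2.9 ± 0.49, 0.00410), and Ndufa4l2 (3.02 ± 0.42, 0.00169) rose. These 6 genes kept their call without each library in turn and with litter as a block (0.0150, 0.0205, 0.000809, 0.00142, 0.0471 and 0.0374).

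EdgeR called 120 genes higher and 63 lower in this comparison, 183 in all, with 2196 at an unadjusted p under 0.05. DESeq2 called 486 and limma-voom 137. For 176 of the 183 the hearts of the genotypes did not overlap, against 10.1% of all genes and 2.86% by chance. These genes too were called on the same hearts, so this is no further support. With litter as a block 78 genes were called, 69 of them among the 183, and all 183 kept their direction. The count was 117, 72 and 106 without Ing4+/- Ing5-/- 1, 2 and 3, 82, 84 and 82 without Ing4+/- 1, 2 and 4, and 461 without Ing5-/- 1. Of 40 called genes that the rule named, 19 kept their call without each library and 22 with litter as a block.

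Ing5-/- and wild-type hearts differ by both Ing5 alleles on a background with both Ing4 alleles. EdgeR called 2 genes, both higher. Fcrls stood at 1.86 ± 1.33 against 0.139 ± 0.122 CPM (3.81 ± 0.62, adjusted p = 0.0440). Cox4i2, a subunit of cytochrome c oxidase that low oxygen induces, stood at 10.03 ± 1.93 against 5.00 ± 0.725 CPM (1.00 ± 0.16, adjusted p = 0.0440). None of 25 glycolysis and hypoxia genes was called, and 7 were higher when adjusted over the list alone. Their median was 0.25 (camera adjusted p = 1.65e-09; adjusted p = 0.337 with an estimated correlation; 0.148 with litter as a block). Vegfa differed by 0.72 ± 0.12 (edgeR adjusted p = 0.0681). None of 18 macrophage genes was called, with 15 higher when adjusted over the list alone and a median of 1.77 (camera adjusted p = 4.39e-12; adjusted p = 0.337 with an estimated correlation). Ing5-/- 1 and 2, of litter 1, had macrophage list means of 2.36 and 2.22 over wild-type, and Ing5-/- 3 and 4, of litters 2 and 7, had 0.56 and 0.50. Alb, a liver gene, stood at 14.6 and 7.33 CPM in Ing5-/- 1 and 2 and at 0 CPM in Ing5-/- 3 and 4. Whether tissue from outside the heart adds to the macrophage values of those hearts was not tested. The epicardium list had a median of 0.24 (camera adjusted p = 0.0924), which was -0.17 without Ing5-/- 1 (adjusted p = 0.00769), and 0.41, 0.48 and 0.27 without Ing5-/- 3, Ing5-/- 4 and wild-type 3 (0.0124, 3.60e-05 and 0.0417). These calls use the preset correlation. With an estimated correlation and all libraries the smallest camera adjusted p of any list was 0.337.

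In the Ing5-/- comparison 1514 genes had an unadjusted p under 0.05, and DESeq2 called 43 genes and limma-voom none. With litter as a block no gene was called by edgeR, and Fcrls (log2 fold change 2.59) and Cox4i2 (0.84) both had an adjusted p of 0.907. No gene was called without any 1 of Ing4+/- Ing5-/- 1 to 4, Ing4+/- 1 to 3, Ing5-/- 1 or wild-type 1 to 4. Without Ing5-/- 2, 3 and 4 the count was 13, 1 and 15, and without Ing4+/- 4 it was 3. Camera called 10 of the 29 lists, and none with an estimated correlation. No litter held both genotypes, so a value within litters cannot be given.

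Ing4+/- and wild-type hearts differ by 1 Ing4 allele. No gene was called by edgeR, with 746 at an unadjusted p under 0.05 and a smallest adjusted p of 0.10. DESeq2 called 3 genes and limma-voom none. Among the genes with small p in edgeR were Cdk2ap1, a regulator of the cell cycle (0.51 ± 0.09, adjusted p = 0.10), and Trim7, a ubiquitin ligase (0.49 ± 0.10, 0.417), neither called. DESeq2 gave them adjusted p of 0.000484 and 0.0268. EdgeR called 1 gene without Ing4+/- 4, Ing5-/- 1 or Ing5-/- 4, and none without any other library. The macrophage list had a median of 0.66 with no member called (camera adjusted p = 0.00631; adjusted p = 0.773 with an estimated correlation), and it lost the camera call without Ing4+/- 1 (0.0712) or 3 (0.0668). The medians of the glycolysis and hypoxia list (-0.05) and of the epicardium list (-0.09) were not called by camera (adjusted p = 0.568 and 0.245).

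Ing4+/- Ing5-/- and Ing5-/- hearts differ by 1 Ing4 allele on a background without Ing5. Dpp6 was the only gene called by edgeR, at 13.0 ± 4.06 against 4.00 ± 0.798 CPM (1.70 ± 0.20, adjusted p = 0.00101; 0.107 with litter as a block). DESeq2 called 19 genes and limma-voom 1, and 1047 had an unadjusted p under 0.05 in edgeR. The count was 2 without Ing4+/- Ing5-/- 1 or Ing5-/- 3, 3 without Ing4+/- Ing5-/- 4 or wild-type 2, and 0 with litter as a block. None of 28 epicardial genes was called, 4 were lower when adjusted over the list alone, and the median was -0.57 (camera adjusted p = 7.50e-08; adjusted p = 0.426 with an estimated correlation). That median was -0.97 within litter 1, which held Ing5-/- 1, and 0.20 within litter 7, and -0.16 without Ing5-/- 1. In litter 7 Ing5-/- 4 had high Xist (400 CPM) and Ing4+/- Ing5-/- 4 had Ddx3y (67.3 CPM), so that pair differed in sex markers too. The glycolysis and hypoxia list had a median of 0.21 (camera adjusted p = 7.50e-08; adjusted p = 0.267 with an estimated correlation), with 0.45 and 0.32 within litters 1 and 7 and 1 member higher when adjusted over the list alone. The macrophage list had a median of 0.50 (camera adjusted p = 3.68e-05; adjusted p = 0.458 with an estimated correlation; 0.104 with litter as a block), with -0.54 and 1.07 within litters 1 and 7. Its camera call was lost without Ing5-/- 4 (median 0.21, adjusted p = 0.0821).

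The interaction tested whether the effect of the Ing4 allele differed between hearts with and without Ing5. EdgeR called no gene, with 928 at an unadjusted p under 0.05 and a smallest adjusted p of 0.135, while DESeq2 called 7 and limma-voom none. EdgeR called 2 genes without Ing4+/- Ing5-/- 1 and 1 without Ing4+/- 4. Camera called 12 lists, 6 in each direction, and none with an estimated correlation (smallest adjusted p = 0.243). The glycolysis and hypoxia list had an interaction median of 0.26 (camera adjusted p = 2.19e-05; adjusted p = 0.490 with an estimated correlation). The epicardium list had -0.57 (camera adjusted p = 0.00320; adjusted p = 0.700 with an estimated correlation), which was -0.09 without Ing5-/- 1 (camera adjusted p = 0.618). The macrophage list was not called (median -0.31 with the test pointing upward, camera adjusted p = 0.471), except without Ing5-/- 1 (median 0.05, adjusted p = 0.0202).

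The effects of Ing5 loss on the backgrounds with 1 and with 2 Ing4 alleles share no library without a block and were compared across genes, which are not independent replicates. They do share litters: 1 and 7 between Ing4+/- Ing5-/- and Ing5-/- hearts, and 4 and 6 between Ing4+/- and wild-type hearts. Differences between litters could therefore move both effects alike, and the values below do not separate this from Ing5 loss. Pearson's r across genes was 0.36 and Spearman's rho 0.27, and r was 0.11 without a filter on low counts. With litter in the model r is not comparable, since no litter held both Ing5-/- and wild-type hearts and that effect is then estimated through the hearts of the other comparison. Of the 183 genes called against Ing4+/- hearts, 170 had the same direction in Ing5-/- against wild-type hearts, with a median of 0.26 in that direction against 0.70. The overlap of called genes was 1 higher gene, Cox4i2, where 0.0152 was expected by chance. The mean signed level of the 183 genes over the wild-type mean was 0.29, 0.38, 0.46 and 0.29 in Ing5-/- 1 to 4, -0.09 to 0.04 in the wild-type and 0.69 to 0.94 in the Ing4+/- Ing5-/- hearts. The 183 genes were selected by their effect in Ing4+/- Ing5-/- hearts, which inflates the median of 0.70 and the levels of 0.69 to 0.94. Their gap to the Ing5-/- values therefore does not show a weaker effect of Ing5 loss with 2 Ing4 alleles. The difference between Ing5-/- and wild-type hearts was 0.36 (two-sided exact permutation p = 0.0286, the smallest that 70 regroupings can give). The regroupings take no account of litter, and no litter held both genotypes. The effects of the Ing4 allele on the backgrounds with and without Ing5 had an r of -0.08 and a rho of -0.04 across genes, with no called gene shared.

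Genes near the targeted alleles were compared with the rest, since flanking segments can come from another strain. Within 10 Mb of Ing4 or Ing5, 6 of 249 genes (2.41%) were called between Ing4+/- Ing5-/- and wild-type hearts, against 128 of 15083 elsewhere (0.849%; Fisher's exact p = 0.0222, adjusted over 5 comparisons 0.0555). A2m, an inhibitor of proteases, rose by 1.94 ± 0.25 from 2.81 ± 0.784 to 10.8 ± 3.74 CPM (edgeR adjusted p = 0.000524; 0.0271 with litter as a block). Vwf, von Willebrand factor of endothelial cells, rose by 0.95 ± 0.16 from 62.6 ± 3.62 to 121 ± 31.3 CPM (adjusted p = 0.00915; 0.200 with litter as a block). Inpp5d, a lipid phosphatase of blood cells (0.89 ± 0.16, adjusted p = 0.00981), lost its call with litter as a block (0.344) and without wild-type 3 (0.0528). Against Ing4+/- hearts 8 of the 249 genes were called (3.21%) and 173 elsewhere (1.15%; Fisher's exact p = 0.00955, adjusted 0.0477). The genes near the targets included Gapdh and Tpi1 of the glycolysis and hypoxia list. Both groups of hearts have the same Ing4 genotype, so a segment beside Ing4 does not differ between them by design. The test pooled the surroundings of Ing4 and Ing5, so it cannot show an effect of a flanking segment in this comparison. These tests depended on the distance: the adjusted p was 0.0307 within 5 Mb and 0.147 within 20 Mb against wild-type, and 0.0131 and 0.162 against Ing4+/- hearts. A test of litter beside genotype called no gene with edgeR (388 at an unadjusted p under 0.05) and none with limma-voom.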

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

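All tests of explanations here were chosen after the result was seen, except the regroupings of the libraries, which were planned. Of 236 groups of 4 values, 19 held a value far from the other 3, where chance gives 11.8 (5%).

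Glycolysis and hypoxia genes were higher in Ing4+/- Ing5-/- than in wild-type hearts. The tables argue against a difference between litters as the whole cause, since the median with litter as a block was 0.44 (camera adjusted p = 1.79e-15). That call uses the preset correlation (adjusted p = 0.0951 with an estimated correlation and no block), and called members went from 7 to 2 with the block. Only litters 4 and 6 held both genotypes, and each pair differed in sex markers. The tables argue likewise against more blood in the hearts (0.48 with the haemoglobin covariate, camera adjusted p = 1.59e-22). Without members within 10 Mb of Ing4 or Ing5 the median was 0.45 (camera adjusted p = 1.04e-19). Few of the 25 members lie there, Gapdh and Tpi1 among them, so leaving them out could hardly change the list. Linked alleles that act on genes elsewhere were not tested. An effect of losing 3 alleles, linked alleles, a delay in development or a difference in oxygen supply may each remain, and these were not tested apart.

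Macrophage genes were also higher in that comparison. The median was 2.39 with litter as a block (camera adjusted p = 1.79e-18) and 2.09 with the haemoglobin covariate (1.52e-20), which argues against litters and blood as the whole cause. These calls use the preset correlation (adjusted p = 0.120 with an estimated correlation and no block), and called members went from 8 to 1 with the block. Only litters 4 and 6 held both genotypes, and each pair differed in sex markers. Within the Ing5-/- genotype the macrophage list stood higher in hearts of litter 1 than in those of litters 2 and 7, so litter may still add to it. A lower share of cardiomyocytes would raise other cell types alike, but the upper quartile of the endothelial list was 0.32 and that of the epicardium list -0.11, against a lower quartile of 1.69 for macrophage genes. More macrophages, or more transcripts per macrophage, may remain, and no test told these apart. A delay in development and tissue from outside the heart were not tested for these genes either.

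Ing5-/- 1 stood apart by genes of other tissues. It had the highest level in 4 of 5 other-tissue lists (neural crest, neurons, endoderm and liver bud, skeletal and pharyngeal muscle, Hox genes). These lists define the pattern, so this level does not test whether tissue from outside the heart was in the sample, which stays open. A wrong genotype label was tested by the genes called between Ing4+/- Ing5-/- and Ing4+/- hearts, whose mean signed level was 0.29 in this heart against at most 0.04 in wild-type hearts. Its Ing5 level of 29.3 CPM lay within the wild-type range of 28.9 to 36.9, so these values point apart and a wrong label stays open, a heterozygous embryo included. No biological explanation was tested.

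In wild-type hearts, Ing4 stood at 28.2 CPM in wild-type 2 against 42.6 to 44.4 in the others. It also lay below all Ing4+/- hearts (32.0 to 36.3 CPM) and all Ing4+/- Ing5-/- hearts (32.5 to 36.2 CPM). This level goes against the wild-type label, which was not tested, so a wrong label stays open for that heart. Upk3b stood at 157 CPM in wild-type 1 against 170.4 to 173 in the others, and Wt1 at 66.4 against 68.1 to 68.2. List levels relative to the wild-type mean were 0.87 for endoderm and liver bud in wild-type 1, and -0.0567 for the ING and MYST complexes and 0.11 for oxidative phosphorylation in wild-type 2.

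In Ing4+/- hearts, the macrophage list stood at -0.30 in Ing4+/- 4 against 0.69 to 0.81 in the others, and C1qc at 0 against 0.977 to 1.17 CPM. The endoderm and liver bud list stood at 1.24 in Ing4+/- 2, and Krt19 at 46.2 CPM in Ing4+/- 3 against 37.1 to 37.4.

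In Ing5-/- hearts, Egln3 stood at 25.5 CPM in Ing5-/- 3 against 16.4 to 17.4, Aldoc at 17.3 against 9.33 to 10.4 and Dpp6 at 5.19 against 3.58 to 3.63. The atrium and inflow list stood at -0.41 in Ing5-/- 2, the skeletal and pharyngeal muscle list at 2.64 in Ing5-/- 1 and the DNA replication list at 0.10 in Ing5-/- 4.

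In Ing4+/- Ing5-/- hearts, Ing5 stood at 25.1 CPM in replicate 2 against 19.2 to 19.9 and Pgk1 at 201 CPM in replicate 3 against 239.9 to 244.8. The retinoic acid list stood at 0.31 in replicate 4 against -0.01 to 0.03.

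Camera ranked 12 lists above or below other genes in the interaction, none with an estimated correlation (smallest adjusted p = 0.243), and fry, which tests a list on its own, called 0 in one direction and 0 in either. Lower medians were -0.57 for epicardium, -0.25 for proepicardium, -0.47 for atrium and inflow, -0.10 for outflow tract, -2.82 for skeletal and pharyngeal muscle and -2.63 for Hox genes. The muscle and Hox lists rest on only 3 of 12 and 8 of 21 listed genes that passed the filter. Among the Hox genes, Hoxa5 stood at 0.255 to 0.683 CPM in wild-type hearts, 3.73 CPM in Ing4+/- 2 and 8.0 CPM in Ing5-/- 1. Higher medians were 0.15 for cardiomyocyte, 0.30 for endothelium, 0.68 for erythroid, 0.26 for glycolysis and hypoxia, 0.10 for oxidative phosphorylation and 0.0768 for extracellular matrix genes. Without Ing5-/- 1 the camera call was lost for epicardium (median -0.09, adjusted p = 0.618) and cardiomyocyte genes (0.0307, 0.157), and without Ing4+/- Ing5-/- 2 for erythroid genes (0.0066, 0.0775). The atrium call was lost without Ing4+/- 1 (0.0600) or 2 (0.0616), Ing4+/- Ing5-/- 2 (0.211), Ing5-/- 3 (0.203) or 4 (0.0959) and wild-type 2 (0.0951) or 4 (0.0834). The oxidative phosphorylation call was lost without Ing4+/- 4 (0.0918), Ing4+/- Ing5-/- 1 (0.184) or 3 (0.102), Ing5-/- 1 (0.0651) or 4 (0.108) and wild-type 2 (0.191). The extracellular matrix call was lost without Ing4+/- 2 (0.113), 3 (0.112) or 4 (0.0918), Ing4+/- Ing5-/- 2 (0.0806) or 3 (0.350), Ing5-/- 3 (0.412) or 4 (0.391) and wild-type 2 (0.106) or 4 (0.104). The outflow tract call held only without Ing4+/- 3, Ing4+/- Ing5-/- 4, Ing5-/- 1 or wild-type 1, and its highest adjusted p was 0.274 without Ing5-/- 3.

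Regrouping the 8 libraries of a comparison gives 35 splits. As many genes as the real split were called in 1 split for Ing4+/- Ing5-/- against wild-type (135; highest other 0) and in 1 against Ing4+/- (183; 0). The real split itself is that 1, the smallest number that 35 splits can give. These splits argue against chance there, as far as hearts can be exchanged between litters, but do not exclude it. For Ing5-/- against wild-type hearts it was 1 split as well (2; 0), but such splits ignore litter, and no litter held both genotypes. Neither gene was called with litter as a block, with log2 fold changes in the same direction (0.84 against 1.0 for Cox4i2 and 2.59 against 3.81 for Fcrls), and the calls were lost without most single libraries. Chance cannot be excluded for Ing4+/- Ing5-/- against Ing5-/- hearts (8 splits; 1 gene; 18). For Ing4+/- against wild-type hearts (35 splits; 0 genes; 0) and for the interaction (100 of 100 drawn splits; 0; 0) a count of 0 fixes the outcome, so the splits decide nothing. The split with 18 genes set Ing4+/- Ing5-/- 1 to 3 with Ing5-/- 4 against the others, and what sets these libraries apart was not tested. Haemoglobin transcripts made up 1.60, 4.68, 1.82 and 3.23% of the reads in those 4 hearts and 0.548 to 1.06% in the other 4. For lists called by camera, chance could not be excluded in any comparison. As many lists were called in 3 splits for Ing4+/- Ing5-/- against wild-type (13; 15), 9 for Ing5-/- (10; 12) and 3 for Ing4+/- against wild-type (7; 8). The numbers were 18 against Ing5-/- (10; 16), 6 against Ing4+/- (10; 14) and 14 of 100 for the interaction (12; 17).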

How the results depend on the processing

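Alternatives were planned, except the fit without the 3 libraries that stood apart, the haemoglobin covariate and leaving out libraries of groups not compared, which were chosen after seeing the data; the cause was not tested unless stated. Of the results run under each setting, 240 kept direction and side of the threshold with DESeq2 size factors, 233 without a filter, 236 with the stricter filter, 227 with the Y-linked covariate and 159 with litter as a block, where 72 lost the threshold with 6 residual degrees of freedom instead of 12.

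Counts in the order Ing4+/- Ing5-/- against wild-type, Ing5-/- against wild-type, Ing4+/- against wild-type, Ing4+/- Ing5-/- against Ing5-/-, against Ing4+/-, and interaction were 325, 43, 3, 19, 486 and 7 with DESeq2, 78, 0, 0, 1, 137 and 0 with limma-voom and 79, 0, 0, 1, 135 and 0 with litter as a random effect. They were 15, 0, 0, 0, 78 and 0 with litter as a block, 12, 0, 0, 0, 57 and 0 with litter and the Y-linked covariate, 164, 0, 0, 1, 186 and 0 with that covariate alone and 128, 0, 0, 1, 189 and 0 with replicate number as a block. Only the groups compared gave 465, 0, 2, 0 and 282. The fit without the 3 libraries gave 315, 4, 4, 1, 198 and 0, and the haemoglobin covariate 90, 0, 0, 1, 135 and 0. Leaving out 1 library gave 37 to 321, 0 to 15, 0 to 1, 1 to 3, 72 to 461 and 0 to 2.

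Ing5 in Ing4+/- Ing5-/- against wild-type hearts was -0.71 with litter as a block and -0.72 with litter and the Y-linked covariate, past no threshold. Ing5 in Ing5-/- against wild-type hearts passed with DESeq2 (-0.51) and without the 3 libraries (-0.64). Ing4 in Ing4+/- Ing5-/- against Ing5-/- hearts passed with DESeq2 (-0.57) and ranged from -0.64 to -0.48 without 1 library. With an estimated correlation the medians of epicardium (-0.29), macrophage (2.15, and 1.59 against Ing4+/-) and glycolysis and hypoxia genes (0.44 and 0.51) were not called. The epicardium median against wild-type was -0.20 with the haemoglobin covariate (adjusted p = 0.0954) and -0.34 to -0.22 without 1 library. Against Ing4+/- it was called with only the groups compared (-0.22), litter (-0.27), litter and the Y-linked covariate (-0.24) and without the 3 libraries (-0.22), and was -0.29 to -0.17 without 1 library. The correlation of Ing5 loss across genes was 0.11 without a filter, 0.56 with litter and 0.54 with litter and the Y-linked covariate; with litter both effects rest in part on the same libraries, so these are not comparable with the value without a block. The share of called genes near the targets was 3.18% within 5 Mb against wild-type and 2.17% within 20 Mb against Ing4+/- hearts.

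Directions turned for erythroid genes with the haemoglobin covariate, which is built from such genes, against wild-type (median -0.0037) and, by the direction of the test, against Ing4+/- hearts (0.0628). They turned with litter as a block for erythroid genes against Ing5-/- hearts (0.0495, by the direction of the test) and in the interaction (-0.40), and for outflow tract genes in the interaction (0.0675, and 0.076 with the Y-linked covariate). The extracellular matrix list in the interaction turned to -0.0690 with litter and the Y-linked covariate. Depth limits genes near 1 CPM.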

Other observations

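The tests of genes on the X chromosome were chosen after the result was seen, and the Xlr genes, an X-linked family, were picked after their values were seen and not tested as a family. Of 7 Xlr genes tested, 4 rose in Ing4+/- Ing5-/- against wild-type hearts: Xlr3a by 1.61 ± 0.31 (edgeR adjusted p = 0.0143), Xlr3b by 1.69 ± 0.32 (0.0167), Xlr4b by 2.44 ± 0.48 (0.0180) and Xlr4c by 2.48 ± 0.51 (0.0229). The other 3, Xlr (1.52 ± 0.40, edgeR adjusted p = 0.0886), Xlr3c (1.31 ± 0.46, 0.243) and Xlr4a (1.78 ± 0.74, 0.368), were not called. Against Ing4+/- hearts Xlr4b rose by 3.30 (edgeR adjusted p = 0.00169), Xlr4c by 3.50 (0.00201), Xlr3a by 1.48 (0.0195) and Xlr3b by 1.34 (0.0436), while Xlr (0.25, 0.817), Xlr3c (0.85, 0.413) and Xlr4a (1.70, 0.313) were not called. Between Ing5-/- and wild-type hearts the values were 1.12 for Xlr3a (0.338), 1.09 for Xlr3b (0.344), 1.40 for Xlr4b (0.402) and 1.17 for Xlr4c (0.500), and none of the 7 was called. Members of this family are nearly identical in sequence, and how shared reads were counted is not known. Of 558 X-linked genes 10 were called against wild-type (1.79%, 8 higher) and 125 of 14776 others (0.846%; Fisher's exact p = 0.0322, adjusted over 2 comparisons 0.0645). Against Ing4+/- hearts 1.61% and 1.17% were called (Fisher's exact p = 0.317). These tests did not take sex markers into account, which were not balanced between Ing4+/- Ing5-/- and wild-type hearts. Xist was high in wild-type 2 and 4 (427 and 398 CPM) but only in Ing4+/- Ing5-/- 2 (595 CPM) of its group. Among Ing4+/- hearts Xist was likewise high in a single heart, Ing4+/- 3 (372 CPM), with 16 CPM in Ing4+/- 4.

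Dpp6 and Cox4i2 had the smallest p between Ing4+/- Ing5-/- and wild-type hearts, at 2.33 ± 0.21 (edgeR adjusted p = 1.18e-05) and 1.68 ± 0.16 (1.70e-05). Cox4i2 stood at 16.1 ± 2.57 against 5.00 ± 0.725 CPM (n = 4).

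Single libraries stood apart. Ing4+/- 4 had reads in 15934 genes, a score of 87.4 on principal component 1, and both Ddx3y (67.5 CPM), which is Y-linked, and Xist (16 CPM), the transcript of the inactive X chromosome. A mixed library or one of low complexity cannot be excluded for this heart. Ing5-/- 1 had 14.6 CPM of Alb, 8.0 of Hoxa5 and 4.78 of Ttr, genes of liver and of more posterior tissue, and Ing5-/- 2 had 7.33 CPM of Alb. Xist stood at 3.35 CPM (103 reads) in Ing5-/- 1 and 1.43 CPM (45 reads) in Ing5-/- 2 beside Ddx3y at 64.4 and 56.9 CPM, against 0 to 0.372 CPM of Xist in 8 other hearts with Ddx3y at 53.4 to 71.0 CPM, Ing4+/- 4 left aside. In Ing4+/- Ing5-/- 2 haemoglobin transcripts made up 4.68% of the reads.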
